A study of Homo sapiens with 6 samples.

How the data were processed

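Gene expression was measured in MDA-MB-231 cells, an established line of triple-negative human breast cancer that is widely used as a model of invasion. Per the labels' protocols, cells were infected with retroviral vectors carrying either of 2 short hairpin RNAs against WASF3, or with control vectors (empty, or with a hairpin against GFP), and single puromycin-resistant clones were expanded. The series design compares 3 knockdown clones with 3 control clones, read here as 1 array for each clone. The hairpin or control vector carried by each clone is not given in the sources used here, so neither entered a test. Total RNA was labelled with biotin after amplification from the polyadenylated end of the transcripts and hybridised to a whole-transcriptome Affymetrix oligonucleotide array, per the labels' protocols.

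The deposited table holds log2 values made by the authors with RMA in Affymetrix Expression Console 1.0, per the submitters' processing notes. RMA subtracts background, sets all arrays to the same distribution and summarises the probes of each probe set, so a change shared by most transcripts would not be seen. The array medians lay between 5.13 and 5.17 on the log2 scale. The number of arrays, 3 per group, limits the precision of every value. Scanner files were not analysed here, and 0 columns of other samples were in the table.

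Probe sets were named through the platform annotation given with the table, and symbols were brought up to date through gene identifiers in a RefSeq gene table of assembly GRCh38.p14. Of the probe sets, 41091 carried 1 gene symbol, 1801 several and 11721 none, and 62 were control probe sets. Of those with 1 symbol, 41037 were matched by identifier and 54 kept the symbol of the annotation. No gene was named from a probe set with several symbols. The RefSeq table was also used for the order of genes along chromosomes, and its positions are not printed because the annotation names no matching build.

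Values were fitted with limma 3.58.1 (lmFit and eBayes without an intensity trend) in R 4.3.3, with group as the only term and all 6 arrays in the fit. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 54613 probe sets that are not controls. The design written before the data were examined spoke of all probe sets. The control probe sets were then left out because they measure no gene of the cells, and keeping them gave the same numbers of called genes. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 19775 genes, and was called when its adjusted p was under 0.05. The moderated fit had 3.49 prior degrees of freedom. Single values were also compared by an exact two-sided permutation test, which cannot go below 0.1 for 3 against 3.

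The genes named in the text were chosen by a rule fixed before the data were examined. It took WASF3, KISS1, MMP9 and NFKBIA, the 12 called genes with the largest increase and the 12 with the largest decrease whose groups did not overlap, and in each gene list up to 4 called members by size of change or, with none called, the 2 with the smallest unadjusted p. Genes outside this rule are said to be so where they appear.

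There were 26 gene lists, also fixed beforehand, with 691 genes of which 629 were measured. They covered the WAVE and ARP2/3 complexes, other actin regulators, the NF-kB pathway and its inhibitors, NF-kB target cytokines, metalloproteinases and other invasion proteases, metastasis suppressors, epithelial markers, mesenchymal markers, extracellular matrix, integrins and focal adhesion, interferon-stimulated genes, MHC and antigen presentation, cell cycle, hypoxia and glycolysis, the JAK and STAT3 axis, RAS and ERK output with immediate early genes, TGF-beta and BMP signalling, cholesterol synthesis, the unfolded protein and ATF4 response, oxidative phosphorylation, ribosomal proteins and cancer-testis antigens. Markers of other cells (luminal breast, melanocytic, leukocyte and basal keratinocyte) formed the remaining lists. Each list was tested with camera of limma, with a preset correlation of 0.01 between genes and adjustment over the lists. The test was repeated with the correlation estimated for each list and with fry, which asks whether the members move on balance in a given direction without comparing them with other genes. Camera with an estimated correlation takes its p-value from the few residual degrees of freedom of the arrays, which raises p-values by itself. With all clones, estimates were below 0.01 for matrix (−0.0169), RAS and ERK (−0.00783), integrin (−0.00107), WAVE (0.00261), protease (0.00298) and hypoxia (0.00450) lists. Higher p-values of these lists in that setting do not come from correlation between genes. Members were counted with adjustment over all probe sets and, separately, adjusted over the list alone.

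RNA quality was followed through the control probe sets for the 3′ and 5′ ends of GAPDH and ACTB, as the mean of the 3′ minus 5′ differences on the log2 scale. The procedure was tested on simulated data built on the 54613 probe sets for the comparison of knockdown with control clones, with 200 probe sets changed in each of 5 simulations. It recovered 68.2% of the changes of 1 and 94.4% of the changes of 2 on the log2 scale, and 4.45% of its calls were false. A shift of 0.4 given to the hypoxia and glycolysis list, among 19775 genes, was called in 5 of 5 simulations, and 0 lists were called where none was shifted. The simulated genes were independent and spread alike in both groups. In the data the estimated correlation reached 0.661 (interferon-stimulated list), so the simulations do not show how often lists of correlated genes are falsely called.

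Alternatives fixed beforehand were an intensity trend, a filter on mean log2 values above 5, the mean of all probe sets of a gene, leaving out probe sets whose names mark them as matching several transcripts, adjustment over 1 probe set per gene, further normalization (quantile, median centring, cyclic loess), array weights, the replicate number as a block, an unadjusted p under 0.05 with a 2-fold change, and leaving out each clone in turn. Alternatives chosen after seeing the data were the control probe sets kept, the 3′ minus 5′ index as a covariate, the removal of called genes near another called gene, and the estimated correlation with each clone left out. The series design speaks of 3 knockdown clones and 3 control clones, while the sample titles give replicate numbers, so 1 clone per array is a reading of these labels. The control arrays were so alike (r = 0.998) that the values cannot settle whether they are separate clones or cultures of the same cells. P-values therefore measure the spread between clones only as far as the labels hold. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.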

Results

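Expression profiles were compared between 3 single clones of MDA-MB-231 breast cancer cells stably expressing a hairpin against WASF3 and 3 control clones. WASF3 encodes a member of the WAVE family, which activates the ARP2/3 complex and branched actin growth at the leading edge of the cell. The comparison asked which transcripts differ when WASF3 is kept low. Values are log2 RMA signals, given as mean ± SD with n = 3 clones per group, and changes are knockdown minus control with the standard error of the limma fit.

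The WASF3 level was lower in each knockdown clone than in any control clone, at 5.24 ± 0.65 in knockdown and 6.59 ± 0.18 in control clones on the only probe set of this gene. The change of −1.35 (SE 0.29) corresponded to 39.2% of the control signal. The clones differed, with 43.8%, 57.5% and 23.8% left in knockdown clones 1, 2 and 3. It missed the threshold over all probe sets (adjusted p = 0.102 in limma). The exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Without knockdown clone 3, the clone with the lowest signal, the WASF3 level differed by −0.99 and passed (adjusted p = 0.0175). WASF2, a paralogue in the WAVE family, fell by 0.81 on the log2 scale on 1 of its 3 probe sets (SE 0.08, adjusted p = 0.0253), from 9.95 ± 0.03 to 9.14 ± 0.05 or 56.9% of the control signal. Its probe set with the highest mean, at 10.4 in control clones, gave −0.55 (SE 0.10, adjusted p = 0.0715) and the other −0.22 (SE 0.12, adjusted p = 0.479). The value of the brightest probe set of WASF2 passed without knockdown clone 1 (adjusted p = 0.0257) or 3 (adjusted p = 0.0450).

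KISS1, a metastasis suppressor that encodes the kisspeptins, read 6.17 ± 1.81 in knockdown and 4.18 ± 0.07 in control clones, a change of 1.99 (SE 0.77) that did not pass (adjusted p = 0.305). The knockdown clones lay far apart, at 4.37, 6.15 and 7.99 in clones 1, 2 and 3. The control level is below the median of the arrays and close to the median level of the leukocyte markers (4.21), so it is not shown to be above background and a fold from it would be uncertain. Without clone 1 the change of KISS1 was 2.89 and passed (adjusted p = 0.0377). MMP9, a secreted gelatinase, gave −0.12 (SE 0.16, adjusted p = 0.802). NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, gave −0.26 on its brightest probe set (SE 0.08, adjusted p = 0.219) and −0.08 on the other (SE 0.09, adjusted p = 0.745).

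**Figure D1:**
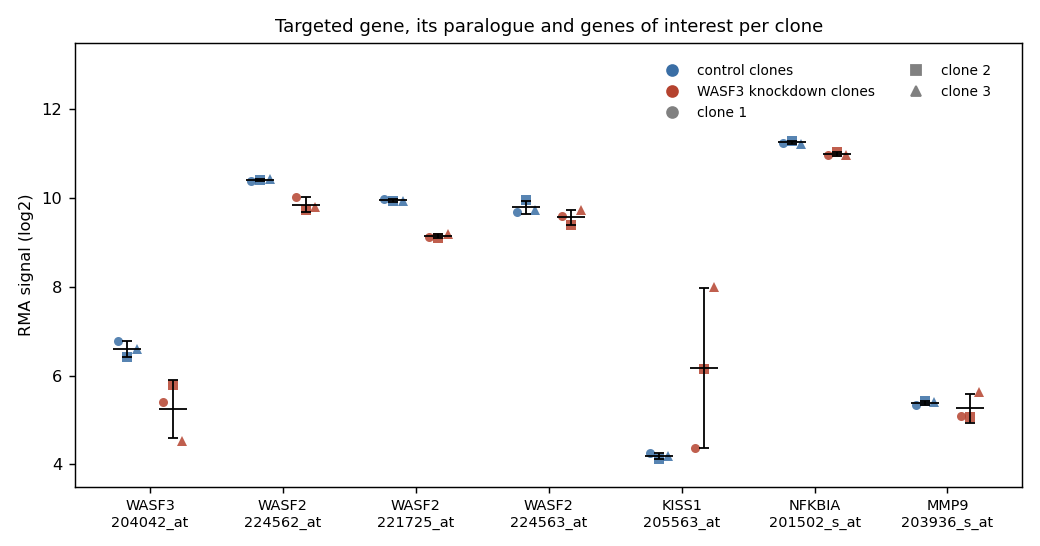
Log2 RMA signal (vertical axis) of WASF3, its paralogue WASF2 on 3 probe sets, KISS1, NFKBIA and MMP9 in each clone, with control clones in blue, knockdown clones in red, marker shape for the clone number, and bars for the mean ± SD of 3 clones. WASF3 means were 6.59 in control and 5.24 in knockdown clones, and the KISS1 values of the knockdown clones spread widely around their mean of 6.17.

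Among transcripts higher in the knockdown clones, the homeodomain transcription factor IRX5 rose 3.18-fold (log2 change 1.67, SE 0.11, adjusted p = 0.00578), from 6.18 ± 0.07 in control to 7.85 ± 0.19 in knockdown clones. PLEKHA7, a protein of the adherens junction, rose 2.88-fold (log2 change 1.53, SE 0.10), and AIF1L, an actin-binding protein, rose 2.54-fold (1.35, SE 0.17). The other genes among the 12 largest increases included GPR137C (1.25), the immunophilin FKBP1B (1.20), the succinate semialdehyde dehydrogenase ALDH5A1 (1.19), GDPD1 (1.18) and the HMG-box factor TOX (1.17). They also held a probe set annotated to the small nucleolar RNA SNORA21 (1.09), the histone demethylase KDM1B (1.04), the aryl hydrocarbon receptor repressor AHRR (1.03) and the noncoding transcript CRIM1-DT (1.00). Because labelling began at the polyadenylated end of transcripts, the value under SNORA21 is not shown to be that of the small nucleolar RNA itself. The adjusted p-values of these 12 genes ran from 0.00578 to 0.0491. GDPD1 had 3 probe sets, of which 2 shared the sign and 1 passed.

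The largest changes were decreases. FAM133A fell by 2.96 on the log2 scale (SE 0.45, adjusted p = 0.0476). The lipid-hydrolysing arylacetamide deacetylase AADAC fell by 2.81 (SE 0.13, adjusted p = 0.00176), from 6.52 ± 0.17 in control to 3.72 ± 0.20 in knockdown clones. The related pseudogene AADACP1 fell by 2.93 (SE 0.09, adjusted p = 9.51e-05). Signal shared between these related sequences makes their separate values uncertain. Also among the 12 largest decreases were the sortilin-family receptor SORCS2 (−1.98), the complement protease C1S (−1.81), the adhesion molecule ICAM1 (−1.71), the endothelial lipase LIPG (−1.65), the proteoglycan SPOCK1 (−1.61) and the trefoil peptide TFF2 (−1.59). The serpin SERPINB4 (−1.92) is nearly identical to SERPINB3, so its value is uncertain. The others were APCDD1L (−2.51) and the nuclear receptor RORA (−1.80), for which 7 of 8 probe sets shared the sign and 1 passed. The knockdown levels of AADAC, SERPINB4 (3.06) and RORA (3.29), and the control level of TOX (3.82), lay below the leukocyte marker level of 4.21 and are not shown to be above background, so the size of these changes is uncertain, as for KISS1. That level is a median, and the knockdown levels of AADACP1 (4.29), FAM133A (4.58) and SPOCK1 (4.60) and the control level of GPR137C (4.38) lay close above it. The same limit holds for their changes.

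In all, 63 genes were higher and 83 lower among 19775 (limma, adjusted p under 0.05), and 11 of the former and 31 of the latter differed at least 2-fold. At an unadjusted p under 0.05 there were 1801 higher and 1516 lower. The groups did not overlap in any of the 146 called genes, which calling on a large change against a small spread favours. Across all genes they did not overlap in 24.7%. Chance gives 10% where all arrays spread alike, but the control arrays were tighter (median SD 0.0863 against 0.157). How much of the excess over 10% comes from this unequal spread was not computed, so the excess is not read as a widespread change. Of the 90 called genes with more than 1 probe set, 72 had the same sign on all of them and 0 had a call in the opposite direction (limma on each probe set). Of the 24 genes named for their size of change, 8 (IRX5, GDPD1, ALDH5A1, KDM1B, AADAC, AADACP1, C1S and TFF2) lay within 10 measured genes of another called gene of the same direction. CRIM1-DT and GPR137C did not, but their neighbours had median changes of 0.43 and 0.28. RORA, SERPINB4 and TOX, with mean log2 values not above 5, were not placed in the gene order and could not be tested for this. Without control clone 1, 2 or 3 the calls fell to 2, 3 and 2 genes, with AADACP1 and AADAC among them each time. The median absolute change of the 146 genes stayed at 0.80, 0.79 and 0.79 in these fits (0.79 with all clones), while their median standard error went from 0.10 to 0.12. They came to 707, 20 and 1225 without knockdown clone 1, 2 or 3, and the direction of all 146 genes held in these 6 fits. The 3′ minus 5′ index of the control probe sets, a sign of RNA quality, was higher in every knockdown clone than in any control clone (1.80 ± 0.27 in knockdown and 1.29 ± 0.17 in control clones, exact permutation p = 0.1). With this index as a covariate, chosen after seeing the data, 1 gene (AADACP1) passed and the median standard error of the 146 genes went from 0.10 to 0.17.

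**Figure D2:**
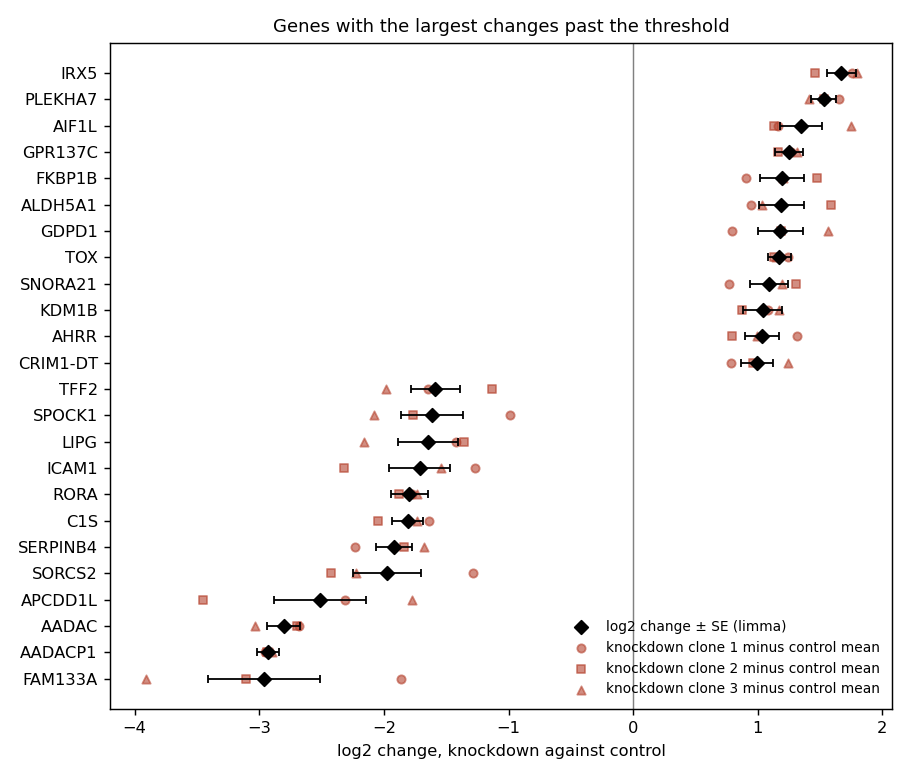
Log2 change between knockdown and control clones (horizontal axis) of the 12 called genes with the largest increase and the 12 with the largest decrease, with black diamonds and bars for the limma estimate ± SE and red markers for each knockdown clone minus the control mean. The changes ran from −2.96 for FAM133A to 1.67 for IRX5, and every clone lay on the same side of 0.

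Genes of hypoxia and glycolysis were lower together in the knockdown clones. ANGPTL4, a hypoxia-induced secreted inhibitor of lipoprotein lipase, fell by 1.23 on the log2 scale (SE 0.08, adjusted p = 0.00578). PFKFB4, a regulator of glycolytic flux, fell by 0.97 (SE 0.09, adjusted p = 0.0172), and EGLN3, a prolyl hydroxylase of the hypoxia response, fell by 0.95 (SE 0.11, adjusted p = 0.0311). Of 34 measured members, 3 fell and 0 rose over all probe sets, 18 fell and 1 rose when adjusted over the list alone, and 32 had a lower mean. Members named after their values were seen included VEGFA (−0.63), the glucose transporter SLC2A1 (−0.63), the glycolytic kinase PGK1 (−0.50) and the hypoxia factor EPAS1 (−0.67). On the probe sets that represent them these 4 passed only when adjusted over the list alone, while 2 of the 6 probe sets of PGK1 passed over all probe sets. HIF1A, which encodes the oxygen-regulated subunit of the same factor family, was the member that went the other way in that count (0.42, SE 0.09, adjusted p = 0.0978 over all probe sets). The list had a median of −0.39, with −0.44, −0.41 and −0.32 in knockdown clones 1, 2 and 3. PFKFB4 was the called member with another called gene of the same direction within 10 measured genes. The list shifted down by camera (adjusted p = 4.12e-13). The shift held with an estimated correlation (adjusted p = 0.0303), with fry (adjusted p = 0.00157) and with the 3′ minus 5′ index as a covariate (adjusted p = 9.69e-05). With an estimated correlation and any single clone left out as well, it was not called (adjusted p from 0.0711 to 0.276), with medians from −0.43 to −0.35. Those fits also had fewer residual degrees of freedom.

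**Figure D3:**
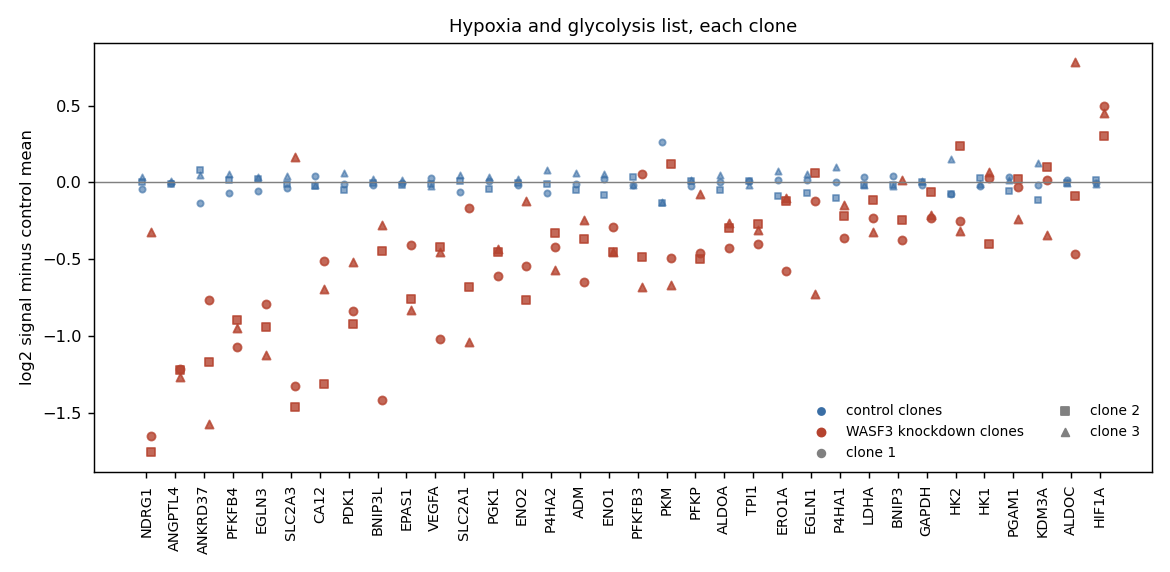
Log2 signal minus the control mean (vertical axis) of each of the 34 measured genes of the hypoxia and glycolysis list, ordered by change, with control clones in blue, knockdown clones in red and marker shape for the clone number. The mean of the knockdown clones was below that of the control clones for 32 of the 34 genes, with HIF1A at 0.42 on the other side.

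Of the matrix and adhesion genes, COL6A3 fell by 1.55 (SE 0.11, adjusted p = 0.00748) and COL5A1 by 1.29 (SE 0.17, adjusted p = 0.0377) on the log2 scale. The laminin chain LAMB3, which has a called gene of the same direction within 10 measured genes, fell by 0.91 and the basement membrane collagen COL4A2 fell by 0.68. Among 31 measured extracellular matrix genes 5 fell and 0 rose, the fifth being COL7A1 (−0.67, named after its value was seen). In this list 7 fell and 1 rose when adjusted over the list alone. The list median was −0.17 (camera adjusted p = 0.000257, adjusted p = 0.107 with an estimated correlation of −0.0169, and fry adjusted p = 0.00307). Of 30 integrin and focal adhesion genes, the fibronectin receptor chain ITGA5 fell by 1.17 (SE 0.15, adjusted p = 0.0368). The vitronectin receptor chain ITGB5 fell by 0.87 (SE 0.09, adjusted p = 0.0310) in a neighbourhood with a median change of −0.23, 0 rose, and 3 fell when adjusted over the list alone. This list had a median of −0.15 and was called by camera (adjusted p = 0.0287) and by fry (adjusted p = 0.0421). It was not called with an estimated correlation (adjusted p = 0.178), without knockdown clone 1 (median −0.11, adjusted p = 0.163) or with the mean of all probe sets (−0.10, adjusted p = 0.0502). Nor was it called without probe sets matching several transcripts (−0.03, adjusted p = 0.198). Metalloproteinases and other invasion proteases had a median of −0.09 (camera adjusted p = 0.0170, adjusted p = 0.178 with an estimated correlation, and adjusted p = 0.157 with fry). None of their 33 measured members passed in limma, while 2 higher and 9 lower had an unadjusted p under 0.05. Adjusted over the list alone, 1 rose and 5 fell, with ADAMTS1, a matrix protease, at 0.65 (adjusted p = 0.0532) and MMP14, the membrane-bound collagenase, at −0.48 (adjusted p = 0.0582). The protease list gave an adjusted p of 0.0606 without knockdown clone 1 (median −0.11) and 0.110 without probe sets matching several transcripts (−0.06). The RNA quality index was higher in the same knockdown clones. With it as a covariate the median was −0.10 for matrix (camera adjusted p = 0.141), −0.07 for integrin (adjusted p = 0.580) and −0.13 for protease genes (adjusted p = 0.210). With mean log2 values above 5 the matrix median was −0.26.

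The list of WAVE and ARP2/3 components, which holds WASF3 itself, had a median of −0.18 over 19 genes (camera adjusted p = 0.0170, adjusted p = 0.178 with an estimated correlation, and adjusted p = 0.0844 with fry). On the probe sets with the highest mean, none passed over all probe sets in limma (1 higher and 6 lower at an unadjusted p under 0.05), although another probe set of WASF2 did (adjusted p = 0.0253). When adjusted over the list alone 4 fell (WASF2, WASF3, BRK1 and RAC1), BRK1 and RAC1 being named after their values were seen. The call was lost without knockdown clone 1 (median −0.22, adjusted p = 0.0525) and with the RNA quality index as a covariate (median −0.20, adjusted p = 0.289), while the medians were no nearer to 0.

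Luminal breast markers had a median of −0.32 over 14 genes (camera adjusted p = 0.0170, adjusted p = 0.679 with an estimated correlation, and adjusted p = 0.325 with fry). The median was −0.16 without knockdown clone 3 and −0.52 without clone 1. With the mean of all probe sets it was −0.18 and the call was lost (adjusted p = 0.0535). None passed over all probe sets in limma, with 1 higher and 6 lower at an unadjusted p under 0.05, and 3 fell when adjusted over the list alone. The trefoil peptide TFF1, an oestrogen-responsive secreted protein, read 9.21 ± 1.41 against 12.2 ± 0.09 (−2.95, SE 0.60, adjusted p = 0.0895), and the keratin KRT8 differed by −0.58 (adjusted p = 0.155). Of 26 TGF-beta and BMP genes, INHBA, an activin subunit, fell by 1.33 (SE 0.15, adjusted p = 0.0311) and 0 rose, and 4 fell when adjusted over the list alone. The median was −0.24 (camera adjusted p = 0.0287, adjusted p = 0.679 with an estimated correlation, and adjusted p = 0.325 with fry). The call was lost without knockdown clone 3 (median −0.09, adjusted p = 0.220) and with the mean of all probe sets (−0.09, adjusted p = 0.0969). Without probe sets matching several transcripts the median was −0.14. Of 28 genes of RAS and ERK output, the feedback inhibitor SPRY4 fell by 0.56 (SE 0.09, adjusted p = 0.0491), 0 rose, and 2 fell when adjusted over the list alone. The median was −0.11 (camera adjusted p = 0.0271, adjusted p = 0.178 with an estimated correlation, and adjusted p = 0.325 with fry). The call was lost without knockdown clone 1 (median −0.04, adjusted p = 0.251) and with the RNA quality index as a covariate (−0.07, adjusted p = 0.782). The median was −0.23 without knockdown clone 3 and −0.17 without probe sets matching several transcripts.

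Of 23 NF-kB target cytokines and adhesion molecules, ICAM1 fell (−1.71, SE 0.24, adjusted p = 0.0430), 0 rose, and 1 rose and 2 fell when adjusted over the list alone. The member that rose in that count was IL11, named after its value was seen (2.34, SE 0.57, adjusted p = 0.128 over all probe sets). The list median was −0.19 and the call held in 10 of 18 settings (camera adjusted p = 0.0380). It was lost with an estimated correlation (adjusted p = 0.679), with fry (adjusted p = 0.325), without knockdown clone 1 (adjusted p = 0.233) or 2 (median −0.03, adjusted p = 0.260) and without control clone 1 (adjusted p = 0.0937). It was also lost with the RNA quality index as a covariate (−0.13, adjusted p = 0.796), with the mean of all probe sets (adjusted p = 0.0969) and without those matching several transcripts (adjusted p = 0.365). Without knockdown clone 3 the median was −0.32. Cholesterol synthesis was the list that shifted up, with a median of 0.23 over 18 genes (camera adjusted p = 0.0380). None of its members passed over all probe sets in limma, and 6 higher and 1 lower had an unadjusted p under 0.05. In this list 3 rose and 1 fell when adjusted over the list alone. The sterol dehydrogenase HSD17B7 gave 0.45 (adjusted p = 0.120) and HMGCS1, the HMG-CoA synthase, 0.55 (adjusted p = 0.124). Of the 2 probe sets of HMGCS1 only 1 had this sign. The call held in 9 of 18 settings. It was lost with an estimated correlation (adjusted p = 0.679), with fry (adjusted p = 0.325), with mean log2 values above 5 (adjusted p = 0.0556) and without probe sets matching several transcripts (median 0.09, adjusted p = 0.0728). Further quantile normalization (0.20, adjusted p = 0.120) and cyclic loess (0.21, adjusted p = 0.105) ended it too. So did leaving out knockdown clone 1 (0.32, adjusted p = 0.0525), knockdown clone 3 (0.10, adjusted p = 0.193) or control clone 2 (0.22, adjusted p = 0.0828). With the RNA quality index as a covariate the median was 0.42 for cholesterol synthesis (camera adjusted p = 0.0369), −0.68 for luminal markers (adjusted p = 0.00126) and −0.43 for TGF-beta and BMP genes (adjusted p = 0.00126).

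The other 16 lists were not called by camera. Where leaving out a clone brought a call in these lists, it was lost with an estimated correlation, with which 0 lists passed in each of those 6 fits. In the epithelial list the mucin MUC1 fell by 1.24 (SE 0.09, adjusted p = 0.00785), and 1 rose and 4 fell when adjusted over the list alone (median −0.06, camera adjusted p = 0.125, 0.0178 without knockdown clone 1, and 0.0201 with the RNA quality index as a covariate, both at the preset correlation, against 0.687 with the estimated correlation of 0.121). Mesenchymal markers had a median of −0.01 and a mean of −0.24 (camera adjusted p = 0.125, and 0.0420 without knockdown clone 2), with 0 passing in limma. There were 0 higher and 6 lower at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. LOX, the collagen crosslinking oxidase, gave −0.81 (adjusted p = 0.0785) and TGFBI −1.07 (adjusted p = 0.158). In the unfolded protein and ATF4 list the stress-induced inhibitor of mTOR signalling DDIT4 fell by 1.16 (SE 0.13, adjusted p = 0.0311), and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.362, and 0.0468 without knockdown clone 3).

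The NF-kB pathway list had 0 called members in limma, 5 higher and 2 lower at an unadjusted p under 0.05, and 3 higher when adjusted over the list alone, among them the kinase CHUK (0.77, adjusted p = 0.0546) and the nuclear regulator NFKBIZ (0.71, adjusted p = 0.0621), which had 1 of 2 probe sets past the threshold. The neighbours of CHUK and NFKBIZ were higher as well, with median changes of 0.29 and 0.38. Its median was −0.03 and its mean 0.09, and camera gave the upward direction (adjusted p = 0.458). Interferon-stimulated genes had medians of 0.20 and 0.52 in knockdown clones 1 and 2 and −0.79 in clone 3. The list median was 0.01 and the mean −0.03, with the downward direction in camera (adjusted p = 0.625). Without knockdown clone 3 the list shifted up with a median of 0.40 (adjusted p = 1.59e-05), and without clone 2 it shifted down (adjusted p = 0.00790). These calls rest on the preset correlation. The estimate for this list was 0.661 (adjusted p = 0.952 with all clones), and with estimated correlations the adjusted p was 0.308 without clone 3 and 0.743 without clone 2. Among its members 0 passed in limma with either adjustment, and 3 higher and 6 lower had an unadjusted p under 0.05, with IFIT5 at 0.61 (adjusted p = 0.162) and PARP14 at −0.65 (adjusted p = 0.191). Cell cycle genes had medians of 0.18, 0.42 and −0.33 in knockdown clones 1, 2 and 3 (camera adjusted p = 0.362, and 1.73e-07 without clone 3, where an estimated correlation gave 0.280). None passed over all probe sets in limma, and 5 higher and 1 lower had an unadjusted p under 0.05. MCM2, a subunit of the replicative helicase, at −0.60 (adjusted p = 0.0621), was the 1 member that fell when adjusted over the list alone. MHC and antigen presentation genes had a median of 0.01 and a mean of 0.05 against a downward direction in camera (adjusted p = 0.906, and 0.00790 without knockdown clone 2). Among them 0 passed in limma with either adjustment. Unadjusted p-values under 0.05 were those of 0 higher and 2 lower genes, the immunoproteasome subunit PSMB10 at −0.56 (adjusted p = 0.182) and the peptide loading protein TAPBP at −0.42 (adjusted p = 0.207).

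In the remaining lists 0 members passed over all probe sets in limma, and 0 passed when adjusted over the list alone apart from the kinase MAP2K4 (0.54, adjusted p = 0.0936) among metastasis suppressors. Counts at an unadjusted p under 0.05 were 2 higher and 2 lower for metastasis suppressors, 3 and 6 for other actin regulators, 1 and 2 for the JAK and STAT3 axis and 2 and 1 for oxidative phosphorylation. They were 1 and 0 for ribosomal proteins, 2 and 0 for cancer-testis antigens, 1 and 1 for melanocytic, 0 and 1 for leukocyte and 0 and 0 for basal keratinocyte markers. Metastasis suppressors had a median of −0.02, a mean of 0.06 and a camera adjusted p of 0.901, with the downward direction. Camera adjusted p-values were 0.811 for other actin regulators, 0.385 for the JAK and STAT3 axis and 0.974 for oxidative phosphorylation. They were 0.114 for ribosomal proteins (0.0351 without knockdown clone 2, 0.0148 with an intensity trend and 0.0131 with cyclic loess, all at the preset correlation, against 0.687 with the estimated correlation of 0.267), 0.731 for cancer-testis antigens, 0.416 for melanocytic, 0.518 for leukocyte and 0.811 for basal keratinocyte markers. The metastasis suppressor NDRG1 gave −1.24 (adjusted p = 0.171). In the JAK and STAT3 list the transcription factor STAT3 gave 0.58 (adjusted p = 0.189) and JUNB −0.43 (adjusted p = 0.239), with 9 members higher and 13 lower by their means. Among other actin regulators the values were 0.42 (adjusted p = 0.122) for WASL, which activates ARP2/3 as WASF3 does, and −0.37 (adjusted p = 0.133) for LIMK1. Only 2 of the 4 probe sets of WASL shared the sign. The melanocytic factor MITF gave 0.82 (adjusted p = 0.166), with 2 of 3 probe sets sharing the sign, and SOX10 −0.22 (adjusted p = 0.291). Of the 9 melanocytic markers 8 had a lower mean. Other genes named from the lists whose neighbours differed in the same direction by a median of over 0.2 were IFIT5 (neighbour median 0.44), MAP2K4 (0.38), STAT3 (0.26), MCM2 (−0.30), PARP14 (−0.23), KRT8 (−0.22), LIMK1 (−0.55) and NDUFB8 (0.26). NDUFB8, of the oxidative phosphorylation list, itself differed by 0.36 (adjusted p = 0.180 in limma).

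**Figure D4:**
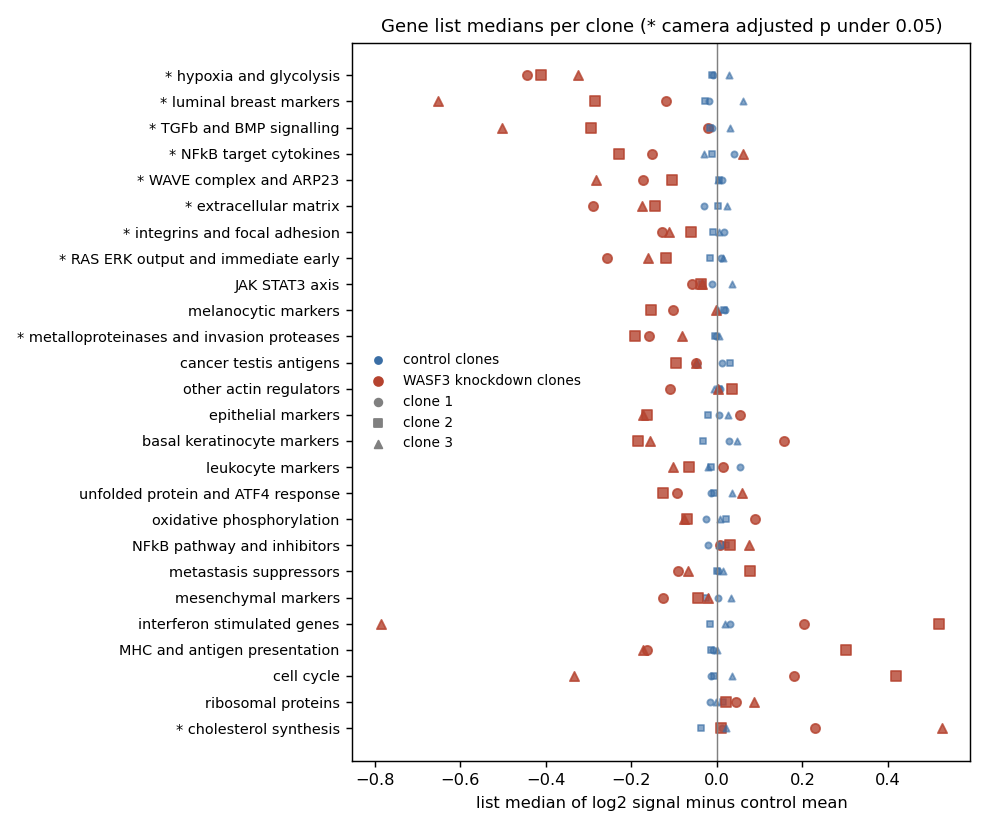
Median over the genes of each list of the log2 signal minus the control mean (horizontal axis) for the 26 gene lists, with control clones in blue, knockdown clones in red, marker shape for the clone number and an asterisk for a camera adjusted p under 0.05. The hypoxia and glycolysis list lay lowest with a median of −0.39, and the interferon-stimulated list ran from −0.79 in knockdown clone 3 to 0.52 in clone 2.

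The control clones were more alike than the knockdown clones. Control arrays correlated across probe sets at 0.998, with 0 to 3 probe sets differing at least 2-fold between any pair. Pairs of knockdown arrays had r from 0.984 to 0.992 and 551 to 2096 such probe sets. Against control arrays, knockdown clones 1 and 2 had r from 0.991 to 0.992 and 478 to 631 such probe sets. For clone 3 these were 0.987 and 1438 to 1478, so knockdown arrays differed from each other about as much as from control arrays. The median SD over probe sets was 0.0863 in control and 0.157 in knockdown clones. Knockdown clone 3 stood apart from the others on the main principal component, which held 42.4% of the variance, at 68.5 against values between −21.0 and 4.42 for the other arrays. The 3′ minus 5′ difference of ACTB was 3.41 ± 0.35 in knockdown and 2.55 ± 0.33 in control clones (exact permutation p = 0.1), and that of GAPDH was 0.19 ± 0.20 and 0.02 ± 0.03 (exact permutation p = 0.2).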

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

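The permutation tests of the added control transcripts were chosen after their values were seen, and no explanation was tested. The Bacillus transcripts added as labelling controls read 9.17 ± 0.18 on knockdown and 8.38 ± 0.27 on control arrays, a difference of 0.79 on the log2 scale (n = 3 per group, exact permutation p = 0.1), and drew attention because these control probe sets lie outside the comparison and were higher on every knockdown array. The bacterial hybridisation controls were higher by 0.31 on the log2 scale (n = 3 per group, exact permutation p = 0.1). Among called probe sets, 35 carried no single gene symbol, so their transcripts stand outside the counts of genes.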

How the results depend on the processing

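The index covariate, the control probe sets kept, the removal of neighbouring called genes and the estimated correlation with a clone left out were chosen after seeing the data. In every alternative fit the 146 called genes kept their sign where measured. Where no cause is given, the cause was not tested. Genes higher and lower were 37 (higher) at an unadjusted p under 0.05 with a 2-fold change, 19 and 44 with an intensity trend, and 97 (higher) with mean log2 values above 5. They were 110 and 128 with the mean of all probe sets, 37 and 51 without probe sets matching several transcripts, 105 (higher) with adjustment over 1 probe set per gene, where fewer tests were adjusted for. They were 419 and 295 with array weights, which favoured the control arrays (0.34 to 2.09). With the index as a covariate they were 0 and 1 in limma (1485 and 1381 at an unadjusted p under 0.05), as the median standard error of the 146 genes went from 0.10 to 0.17 and their median change from 0.79 to 0.81. Leaving out each clone gave 0 to 784 higher and 2 to 441 lower, with 0 higher without each control clone (1141, 1160 and 1302 at an unadjusted p under 0.05), and 5 to 13 lists. Shifted lists numbered 1 with an estimated correlation (0 with any clone left out as well), 3 with fry, 6 with the mean of all probe sets, 6 without probe sets matching several transcripts and 5 with the index. Hypoxia and glycolysis was past the threshold in 18 of 18 settings that change 1 choice (adjusted p from 2.29e-14 to 0.0303), but not with an estimated correlation and a clone left out (0.0711 to 0.276). The WASF3 level was −1.16 and past the threshold with array weights (adjusted p = 0.0359; 0.0175 to 0.420 over the alternatives) and ran from −1.63 to −0.99 without each clone. The RNA quality difference was 0.16 for GAPDH alone and 0.86 for ACTB alone. The interferon-stimulated list turned from the downward to the upward direction in camera without knockdown clone 3 (median 0.40 against 0.01; −0.22 to 0.40 over the 6 clones left out), and MMP9 reversed to 0.013 with the index (adjusted p = 0.991). Further normalization left the counts of genes and lists within 1.5 times, but cholesterol synthesis lost its call with quantile normalization (adjusted p = 0.120) and cyclic loess (adjusted p = 0.105).

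The clone numbers do not pair the samples: deviations of same-numbered clones correlated at −0.0696, −0.0957 and −0.0417, and 0 of 6 arrays correlated best with their own number. With the replicate block 0 genes were higher and 3 lower in limma (1595 and 1225 at an unadjusted p under 0.05), 10 lists were shifted, and the WASF3 level kept −1.35 (adjusted p = 0.186).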

Other observations

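The tests of WASF3 signal on the WASF2 probe sets, and of the neighbours of called genes on probe sets that match a single transcript, were chosen after the results were seen, and that of RNA quality on uncalled neighbours after the same test on called genes. Some called genes stood side by side along the chromosomes. In 5 runs of at least 3 called genes of the same direction, 17 genes were called. Between POM121 and RFC2, 19 of 21 measured genes were lower, among them the called BUD23 and STX1A, and the run medians were −0.39, −0.48 and −0.65 in knockdown clones 1, 2 and 3. Between STYXL1 and GSAP, 10 of 11 genes were lower, with the malate dehydrogenase MDH2 and the small heat shock protein HSPB1 called. Between CPVL and PLEKHA8 all 6 measured genes were lower, with SCRN1 called as well. Between ANKRD40 and COIL all 16 measured genes were higher, with medians of 0.41, 0.51 and 0.52 in knockdown clones 1, 2 and 3, and between GMPR and ALDH5A1, a run that holds KDM1B, 15 of 20 were higher. These genes were named after their values were seen.

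Of 139 called genes with a place in the gene order, 43 (30.9%) had another called gene of the same direction within 10 measured genes, where 1000 shuffled orders gave a median of 10.1% and at most 23.0%. Uncalled neighbours of these genes moved the same way, with a median signed change of 0.24 against at most 0.08 in shuffled orders, which is consistent with a copy number difference that the knockdown clones share, a hypothesis that expression alone leaves open. For the uncalled neighbours, the within-group slope on the 3′ minus 5′ index predicted a share of −0.274 of the shift. In fits without 1 clone this share ran from −0.397 to −0.0340. For the called genes the share was −0.050 (−0.0890 to 0.00356). Calling favours a small spread within groups and so a small share. Because the index did not overlap between the groups, neither share can exclude RNA quality. Probe sets that match several transcripts gave a mixed answer. Without them the share was 18.3%, inside the range of the shuffled orders, which by the bound set before counts for them. With neighbours measured on other probe sets the median signed change was 0.22 (95% bootstrap interval 0.18 to 0.25) against at most 0.05 in shuffled orders. That later test kept called genes picked with such probe sets included, so this explanation is not excluded. A regional effect of lower WASF3 on chromatin is a further hypothesis that remains open and was not tested.

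For the hypoxia and glycolysis list, the within-group slope on the 3′ minus 5′ index predicted a share of 0.136 of the change (0.0386 to 0.236 in fits without 1 clone), under the bound of 0.5 set before. Because the index did not overlap between the groups, this share cannot exclude RNA quality. With members in shifted neighbourhoods left out, 32 of 34 remained, 30 of them lower, with a median of −0.36 (95% bootstrap interval over genes −0.50 to −0.26). A shared copy number difference in the members' own neighbourhoods therefore does not account for the list. Copy number differences elsewhere that act on these genes were not tested. The interval over genes does not measure the spread between clones. The list median was below −0.2 in 3 of 3 knockdown clones, so it does not rest on a single clone. A lower hypoxia programme when WASF3 is kept low remains a hypothesis, and the 10 splits of the clones are too few to exclude chance. A difference in cell density or oxygen at harvest between the groups could give the same genes and was not tested.

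For WASF2, the 20 nearest measured genes had a median change of −0.12 (95% bootstrap interval over genes −0.30 to −0.04), and because this interval spans the bound of −0.2 a copy number difference at the locus cannot be told apart from a change of WASF2 itself. Signal of the WASF3 transcript on the WASF2 probe sets stays open too: on the linear scale the called WASF2 probe set dropped 7.50 times as far as that of WASF3, but probe sets differ in affinity, so this ratio decides nothing. A hairpin that also acts on WASF2 remains a candidate explanation, which was not tested because the hairpin of each clone is not given in the sources used here.

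With 6 clones there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 63 genes higher, 83 lower and 10 lists. It was the 1 split of the 10 with as many, since each other split gave 0 genes in limma (268 to 994 at an unadjusted p under 0.05) and 2 to 7 lists. List calls by camera at the preset correlation thus also arose in every grouping that mixed knockdown and control clones. Mixed groupings keep part of any group difference and the differences between knockdown clones, so their list calls are not a count of false calls. A group difference also widens the spread within mixed groups, which works against calls of genes there.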
